A study of Oryctolagus cuniculus with 9 samples.

How the data were processed

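Polyadenylated RNA from rabbit urethral tissue was sequenced in 9 libraries. The labels do not say whether the libraries came from separate animals, so p-values here measure the spread between these libraries. RNA was purified on spin columns and made into libraries with a template-switching mRNA kit, per the labels' protocols. The sample titles carry 3 codes, S6, S7 and S9, with 3 libraries each, and the number after the code was used as the replicate name. What the codes stand for, which of them is a control, and whether the number names an animal are not given in the sources used here. Libraries are written as code and number, for example S6_2.

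The deposited counts are whole numbers of reads per gene, not normalized. Per the submitters' processing notes, the tools fastp, HISAT2 and HTSeq were used, with no version given. The genome build and the strand setting of the counting are not given in the sources used here. The authors also deposited FPKM values for the same libraries. In 172953 of 172961 values above 0, the FPKM equalled the count divided by the column total and by a gene length that was whole within a relative tolerance of 1e-06, and this length was the same in each library for all 22619 genes with a count. The FPKM values therefore hold the same reads as the counts and were used for an alternative test and for gene lengths. All columns were mapped to samples by their names.

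The table held 28788 gene rows, of which 12867 carried a LOC number in place of a symbol. The gene IDs of 8417 of these were found in the RefSeq table for assembly mOryCun1.1, which gave 515 of them a symbol not used by another row. No coordinates were used, since the build behind the counts is unknown. Total counts lay between 35127085 and 36832773 per library. No pair of libraries held identical values. Pearson's r of log2 CPM across genes ran from 0.924 to 0.957 within groups and from 0.868 to 0.953 between groups, so the ranges overlapped. Genes are not independent replicates, and these correlations describe the libraries only.

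Before the data were examined, the tests, the alternatives, 31 gene lists and the rule for named genes were fixed. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 17102. Counts were scaled by TMM, and 1 model with the 3 groups was fitted with edgeR's robust quasi-likelihood method (edgeR 4.0.16 in R 4.3.3). It had 6 residual degrees of freedom before dispersions were shared between genes. Each pair of groups was compared by a contrast, and the 3 groups together by an F test. P-values were adjusted by Benjamini-Hochberg within each test, and 0.05 was the threshold. Levels are TMM-scaled CPM, given as mean ± SD of the 3 libraries of a group. Standard errors of log2 fold changes were derived from the fold change and its F statistic. The biological coefficient of variation was 41.9%.

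Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Adjustment was over all 90 tests of 30 lists in 3 comparisons, and lists with under 5 tested members were not tested. camera was repeated with an estimated correlation, and fry gave a directional and a mixed test. Some genes, among them COL14A1, COL17A1, DCN, LUM and MMP9, stood in more than 1 list. Counts of members "adjusted over the list alone" used the members' p-values only.

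Named genes were, for each comparison, up to 6 higher and 6 lower genes with the largest log2 fold change among called genes with a symbol, a mean of at least 5 CPM in the higher group and groups that did not overlap. To these came the 3 members with the smallest p of each list that passed camera, and 14 genes named in each comparison (COL1A1, COL3A1, FN1, ACTA2, MYH11, TGFB1, KRT5, KRT13, UPK1B, IL1B, CD163, PECAM1, VEGFA and MKI67). SPP1, CNP and TIMP3 are named as members that moved against their list. PDGFC, FMOD, LTBP2, NEB, KRT18, DST, KRT15, LIPE, PSCA, CDH3, CD36 and DGAT2 were named for S9 against S6, and the mitochondrially encoded genes for the split of the libraries, after their values were seen. For a gene with 0 counts in a group the fold is a bound against a floor of 3 counts over the group, and for 1 to 3 counts a ratio with an exact 95% interval. Intervals and floors cover counting error only. Reads of near-identical genes, such as serum amyloid A or MHC genes, can be split between copies, and overlapping genes cannot be told apart here.

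Alternatives set beforehand were DESeq2 size factors, upper-quartile scaling, no filter, at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with sample weights, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1), a replicate block, the 2 groups of a comparison alone, a fold minimum of 1 on the log2 scale, and each library left out. Chosen after seeing the data were a length correction (a spline with 5 degrees of freedom on log length per library), a term for libraries with few mitochondrial counts, the 6 libraries with many, mitochondrial genes left out, and S6_3 and S7_3 left out. The computations were tested on simulated counts with the real means and library sizes. Each gene was drawn independently, so genes did not vary together between libraries, and the rates of false calls need not hold for the real data. For S9 against S6, with 100 genes changed by each fold among 16784 tested, edgeR recovered 17% of the 2-fold and 59% of the 4-fold genes, and 4 of its 80 calls were false. On 16743 genes DESeq2 recovered 50% and 83%, with 64 false among 200 calls. On 16784 genes limma-voom recovered 16% and 57%, with 2 false among 75 calls. For S7 against S6, with no change simulated, edgeR called 0 genes. Figures were drawn with matplotlib.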

Results

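The series comes from work on a hydrogel stent for repair of the rabbit urethra, and the sequencing was meant to examine how the stent acts on repair. Gene counts were available for 9 libraries of urethral tissue, 3 each of the groups S6, S7 and S9. The labels do not say which treatment, time or animal a code marks, so the comparisons are given as differences between codes, with no group taken as the control. Each library held between 35127085 and 36832773 counts, spread over 19025 to 19417 genes. Depth thus hardly differed between libraries. Levels below are CPM, as mean ± SD with n = 3 per group. Along the first principal component of the 2000 most variable genes, with 36.6% of the variance, the S6 libraries lay at -25.9, -77.0 and -60.5, the S7 libraries at 33.7, -19.8 and -0.591, and the S9 libraries at 59.9, 52.5 and 37.7.

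The libraries also split in a way that the groups do not explain. In S6_4, S7_3 and S9_4, which is 1 library of each group, ATP6 lay between 21.5 and 25.9 CPM, against 1946 to 3258 CPM in the other 6. ND1, COX1, COX2, COX3, ATP8, ND4L and ND6 were low in the same libraries, while CYTB, ND4 and ND5 were not. Mitochondrially encoded genes took 0.243% to 0.419% of the counts there and 0.910% to 1.52% elsewhere. Because the split crosses the groups, each comparison was repeated in the 6 libraries with high mitochondrial counts, and the other class has 1 library per group and allows no test.

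**Figure D1:**
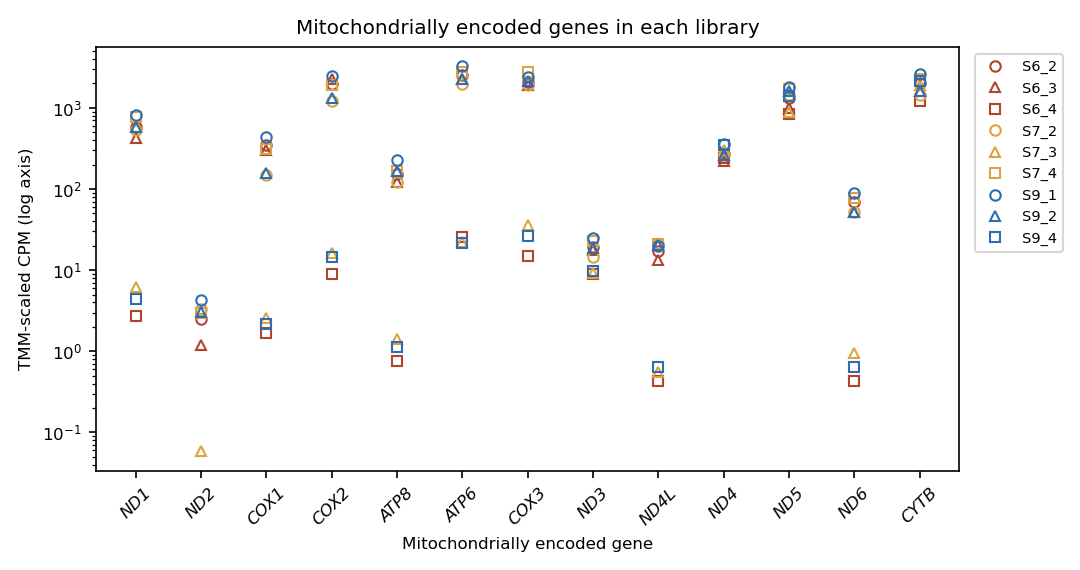
TMM-scaled CPM of the 13 mitochondrially encoded genes, on a log axis, with 1 symbol per library. In S6_4, S7_3 and S9_4 most of these genes lay far below the other 6 libraries, while CYTB, ND4 and ND5 did not; the ND2 values of S6_4 and S9_4 were 0 and are not drawn.

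S9 and S6 differed most. Neutrophil and inflammatory genes were far lower in S9. S100A12, a calcium-binding protein abundant in neutrophils, was at 468 ± 129 CPM in S9 and 7522 ± 2706 CPM in S6, and the cytokine IL1B was at 0.959 ± 0.311 and 33.3 ± 19.2 CPM. Smooth muscle genes were higher in S9, among them MYH11, the smooth muscle myosin heavy chain, at 4363 ± 1376 CPM against 856 ± 434 CPM. By edgeR's quasi-likelihood test 2115 of 17102 genes differed at an adjusted p below 0.05, with 1030 higher and 1085 lower in S9, and 1428 of them differed by at least 1 on the log2 scale. Many of these calls lay near the threshold. The edgeR adjusted p was between 0.03 and 0.05 for 1135 of them, below 0.02 for 325 and below 0.01 for 14. The 3 libraries of S9 lay apart from the 3 of S6 in 35.5% of genes. Over the 10 possible splits of 6 libraries into 3 and 3, the mean share is about 10%. Genes vary together, so the share of a single split can lie far from that mean, and the excess was not tested. The count of called genes varied with the library left out. By edgeR it was 2076 without S7_3, 2056 without S6_2, 2043 without S7_2 and 1947 without S9_4, but 1197 without S7_4, which is in neither group, 1025 without S6_3, 89 without S6_4, 4 without S9_2 and 0 without S9_1, where 3994 genes had an unadjusted p below 0.05. It was 7 in the 6 libraries with high mitochondrial counts. With a term for the mitochondrial class in the fit of all 9 libraries it was 2136, of which 1835 were among the 2115. DESeq2 called 4112 genes and limma-voom 4061. In each of these fits 100% of the 2115 genes that were tested had the same sign of the log2 fold change. This was nearly fixed beforehand, since the fits share libraries with the fit that picked the genes. For 2099 of the 2115 the S9 libraries lay apart from the S6 libraries.

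Among the genes with the largest differences, those higher in S9 were SCGB3A1, a small secreted protein of mucosal epithelia (58.9 ± 37.7 against 1.02 ± 0.565 CPM, log2 fold change 5.84, SE 0.75, edgeR adjusted p = 0.0132), MYOC (log2 fold change 4.30), the methyltransferase INMT (4.24), the neuroendocrine granule protein CHGA (3.77), the mesenchymal transcription factor TCF21 (3.28) and VIPR2, a receptor for vasoactive intestinal peptide (3.23). Those lower in S9 were NOX1, an NADPH oxidase, CA12, a carbonic anhydrase, the phospholipase PLA2G4D, the epithelial cytokine IL17C, the protease inhibitor SERPINA5 and the chemokine CCL17. NOX1 had 3 counts over the 3 S9 libraries and 4770 over those of S6, a ratio of 1662 with a 95% counting interval from 568 to 8060. IL17C had 3 and 1000 counts, a ratio of 348 with an interval from 119 to 1692. PLA2G4D was at 0.0441 ± 0.0404 CPM in S9 and 18.1 ± 7.40 CPM in S6 (log2 fold change -8.57, SE 0.91, edgeR adjusted p = 0.00941). SERPINA5 and CCL17 varied widely within S6, at 34.7 ± 51.4 and 15.1 ± 24.8 CPM.

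Leukocyte and interferon lists passed camera as lower in S9 than in S6 with the preset correlation. With an estimated correlation the adjusted p was 0.0255 for the cytokines and 0.453 to 0.484 for the 5 other lists. Of 17 inflammatory cytokines and mediators 10 were called lower, with a list median of -3.85 on the log2 scale, and 14 were lower when adjusted over the list alone. The chemokine CXCL8 was at 1.07 ± 0.669 against 34.2 ± 14.2 CPM (log2 fold change -5.00, SE 0.67, edgeR adjusted p = 0.0132), and TNF at 0.428 ± 0.138 against 3.62 ± 1.15 CPM. The preset correlation gave this list an adjusted p of 3.3e-09. Of 13 neutrophil genes 10 were called lower (median -3.70), with S100A9 at 74.6 ± 39.3 against 3469 ± 778 CPM and S100A8 at 27.9 ± 13.8 against 1232 ± 343 CPM. Of 23 macrophage genes 11 were called lower (median -1.66), with the lysosomal protein CD68 at 26.1 ± 9.60 against 180 ± 39.2 CPM, the signalling adaptor TYROBP at 27.3 ± 5.47 against 127 ± 74.4 CPM and the scavenger receptor CD163 at 30.7 ± 11.3 against 141 ± 106 CPM. SPP1 was the only member of that list with a positive log2 fold change, at 4115 ± 2182 against 1273 ± 1292 CPM, and was not called (edgeR adjusted p = 0.215). Of 19 T and NK cell genes 5 were called lower (median -1.94), among them CD3G, CD28 and CD247. The T and NK cell list level was 1.94 in S6_3 and 1.17 in S6_4 but -0.022 in S6_2, below the 0.048 of S9_4, so the groups overlapped, and without S6_3 the median was -1.42. Of 14 B and plasma cell genes 6 were called lower (median -2.30), among them CD79B, CD22 and MZB1. Of 20 interferon response genes 9 were called lower (median -1.27), with OASL, an antiviral gene, at 8.19 ± 5.11 against 87.0 ± 12.7 CPM, IFIT3 at 54.8 ± 10.5 against 201 ± 25.8 CPM and IFIH1 at 46.8 ± 5.74 against 96.5 ± 6.74 CPM. Adjusted over the list alone, 11 neutrophil, 15 macrophage, 15 T and NK cell, 11 B and plasma cell and 17 interferon genes were lower.

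**Figure D2:**
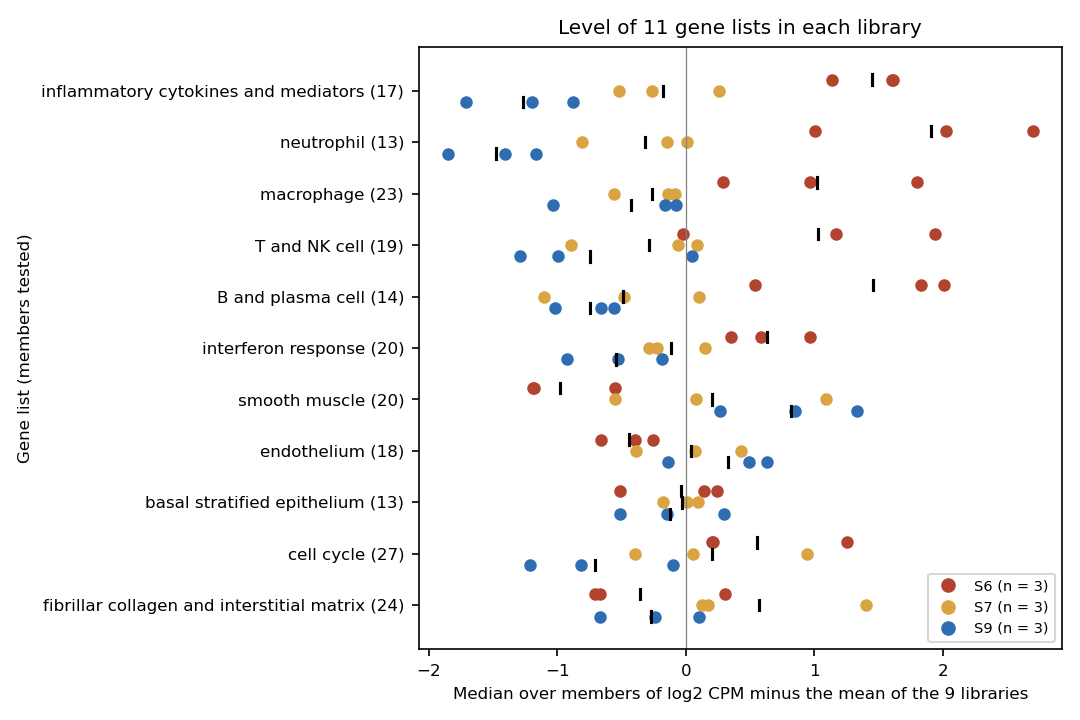
Level of 11 gene lists in each library: the median over tested members of log2 CPM minus the gene's mean over the 9 libraries, with a point per library and a black bar at the mean of each group of 3. The neutrophil list lay between 1.0 and 2.70 in S6 and between -1.85 and -1.17 in S9, while smooth muscle lay between -1.19 and -0.55 in S6 and between 0.26 and 1.34 in S9.

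The lists of muscle, vessels, matrix support and nerve passed camera as higher in S9 than in S6 with the preset correlation, and the adjusted p of these 6 lists was 0.453 to 0.586 with an estimated correlation. All 20 smooth muscle genes had a positive log2 fold change (median 1.91), 11 were called over all genes, and 20 were called when adjusted over the list alone. The actin ACTA2 was at 2104 ± 778 against 599 ± 127 CPM (log2 fold change 1.81, SE 0.41, edgeR adjusted p = 0.0293), MYOCD, a transcriptional activator of smooth muscle genes, at 67.5 ± 31.6 against 14.1 ± 0.634 CPM, and SMTN at 410 ± 91.0 against 144 ± 5.84 CPM. Of 18 endothelial genes 5 were called higher (median 0.81), among them FLT4, a receptor of lymphatic endothelium, ROBO4 and the tight junction gene CLDN5, while PECAM1, at 238 ± 66.4 against 219 ± 36.1 CPM, was not called. Among 22 basement membrane genes 5 were called higher (median 0.76), including the laminin chains LAMB3, LAMC1 and LAMA2. MFAP5 alone was called, higher, of 15 fibroblast genes (median 0.40). The Schwann cell and nerve list (median 1.21) had 3 of 14 members higher, SOX10, NCAM1 and NGFR, and CNP lower. Adjusted over the list alone, 5 endothelial, 9 basement membrane, 1 fibroblast and 6 Schwann cell and nerve genes were higher, and 1 of the last was lower. The repair growth factors (median 0.43) had PDGFA, VEGFD and PDGFC called higher and HBEGF lower among 22, and 9 higher and 1 lower when adjusted over the list alone. The fibroblast call was lost without S6_4 (median 0.24, adjusted p = 0.10) and in the 6 libraries with high mitochondrial counts (median 0.27, adjusted p = 0.0626), and the Schwann cell call without S6_3 (median 1.0, adjusted p = 0.0778). The growth factor call was lost without S6_3 (median 0.31, adjusted p = 0.0852), without S9_1 (0.24 and 0.0551), with a correction for gene length (0.30 and 0.0701) and without both S6_3 and S7_3 (0.28 and 0.0841), and over its alternatives the adjusted p ran from 0.00112 to 0.453.

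A further 8 lists, of metabolism, stress, proteolysis, secretion and division, passed camera as lower in S9 than in S6 with the preset correlation, while most of their members were not called. With an estimated correlation their adjusted p was 0.453 to 0.528. Of 21 glycolysis and hypoxia genes 7 were called lower (median -0.85), with hexokinase HK2 at 10.4 ± 1.57 against 48.9 ± 6.46 CPM, TPI1 at 322 ± 25.4 against 579 ± 58.6 CPM and ALDOA at 657 ± 116 against 1220 ± 84.4 CPM. In the antioxidant list 6 of 19 were lower (median -0.78), with catalase (CAT) at 148 ± 10.3 against 254 ± 25.8 CPM, beside GPX2 and GPX1. Among proteases and inhibitors (median -1.07) 6 of 20 were lower, including the collagenase MMP1 at 0.545 ± 0.129 against 31.7 ± 15.4 CPM, PLAT and MMP9, and the inhibitor TIMP3 was higher. Of 12 secretion genes 4 were lower (median -1.07), with the trefoil peptide TFF1 at 0.377 ± 0.197 against 76.7 ± 31.8 CPM, TFF2 at 1.71 ± 1.14 against 186 ± 108 CPM and WFDC2 at 261 ± 18.4 against 924 ± 272 CPM. All 27 cell cycle genes had a negative log2 fold change (median -1.35), but only AURKA, AURKB and UBE2C were called, and 13 when adjusted over the list alone. Of 41 nuclear oxidative phosphorylation genes 5 were called lower (median -0.40), among them NDUFC2, NDUFB8 and COX6A1. Of the unfolded protein response DNAJC3 and SDF2L1 were lower among 20 (median -0.29), and of 19 immediate early and heat shock genes 4 were lower, including JUNB and BTG2, and HSPH1 was higher (median -0.44). Adjusted over the list alone, 9 glycolysis, 8 antioxidant, 7 protease, 4 secretion, 7 oxidative phosphorylation, 2 unfolded protein and 8 immediate early genes were lower, and 1 glycolysis, 1 antioxidant, 3 protease and 1 immediate early genes were higher. Gene length went partly with the groups compared. In the shortest decile the median level, relative to the mean of the 9 libraries, was -0.14, -0.12 and -0.13 in the S9 libraries and -0.035, 0.45 and 0.034 in S6_2, S6_3 and S6_4. In the longest it was 0.27, 0.16 and 0.12 in S9 and 0.015, -0.29 and -0.11 in S6. Across genes, which are not independent replicates, Spearman's rho of length with the log2 fold change was 0.240. With a length correction the oxidative phosphorylation list had a median of -0.10 (adjusted p = 0.0508, with alternatives from 2.3e-08 to 0.491) and the unfolded protein list -0.18 (0.0989, from 0.00156 to 0.491), and neither passed. The protease call was lost without S6_3 (median -0.66, adjusted p = 0.0882), without S9_4 (-0.75 and 0.0675), without both S6_3 and S7_3 (-0.69 and 0.0733) and with at least 1 CPM in 3 libraries (-1.06 and 0.0538). The immediate early call was lost without S9_4 (median -0.27, adjusted p = 0.0825), and with a median that hardly moved without S6_2 (-0.45 and 0.0611) and in the 6 libraries with high mitochondrial counts (-0.45 and 0.114). The unfolded protein call, whose groups overlapped in list level, was lost without S6_3 (median -0.18, adjusted p = 0.0822), S6_4 (-0.25 and 0.117) or S9_1 (-0.21 and 0.0778), without both S6_3 and S7_3 (-0.21 and 0.0707) and in the 6 libraries (-0.30 and 0.140). Other calls stayed but their medians moved. Without S6_3 the median was -0.88 for the cell cycle and -0.23 for oxidative phosphorylation (-0.26 without both S6_3 and S7_3), without S6_2 -0.67 for secretion and -0.50 for the unfolded protein response, and without S9_1 -1.08 for immediate early genes.

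The collagen lists, and the epithelial lists apart from secretion, did not pass the test between S9 and S6. Of 24 fibrillar collagen and matrix genes only FMOD was called, and the list did not pass camera (median 0.090, mean -0.61, though camera placed it higher, adjusted p = 0.695). COL1A1 was at 12113 ± 2022 against 9854 ± 2708 CPM (log2 fold change 0.30, SE 0.39, edgeR adjusted p = 0.650) and COL3A1 at 15136 ± 4765 against 11351 ± 2676 CPM. FN1, TGFB1, KRT5, KRT13, VEGFA, MKI67 and UPK1B were not called, with UPK1B, a urothelial membrane protein, at a log2 fold change of 2.22 (SE 0.74, edgeR adjusted p = 0.0787). The other lists that did not pass were collagen crosslinking (median 0.068, mean -0.17), the TGF-beta pathway (0.12), skeletal muscle (0.047), urothelium (-0.29), basal stratified epithelium (-0.19, though camera placed it higher), squamous differentiation (-0.30), epithelial junctions (-0.31), mitochondrially encoded genes (0.39) and adipocyte genes (-0.68), with camera adjusted p between 0.135 and 0.876. Members called in these lists were LTBP2, NEB, KRT18, DST, KRT15 and LIPE, higher in S9, and PSCA, CDH3, CD36 and DGAT2, lower. Adjusted over the list alone, 3 TGF-beta, 2 skeletal muscle, 2 urothelial, 2 basal and 1 adipocyte genes were higher, and 3 urothelial, 1 junction and 3 adipocyte genes were lower. Only 3 erythroid genes were tested, too few for camera. Across all 3 comparisons 55 of 90 list tests passed with the preset correlation and 2 with an estimated one. Under 99 other groupings of the 9 libraries the preset correlation passed a median of 39 list tests.

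**Figure D3:**
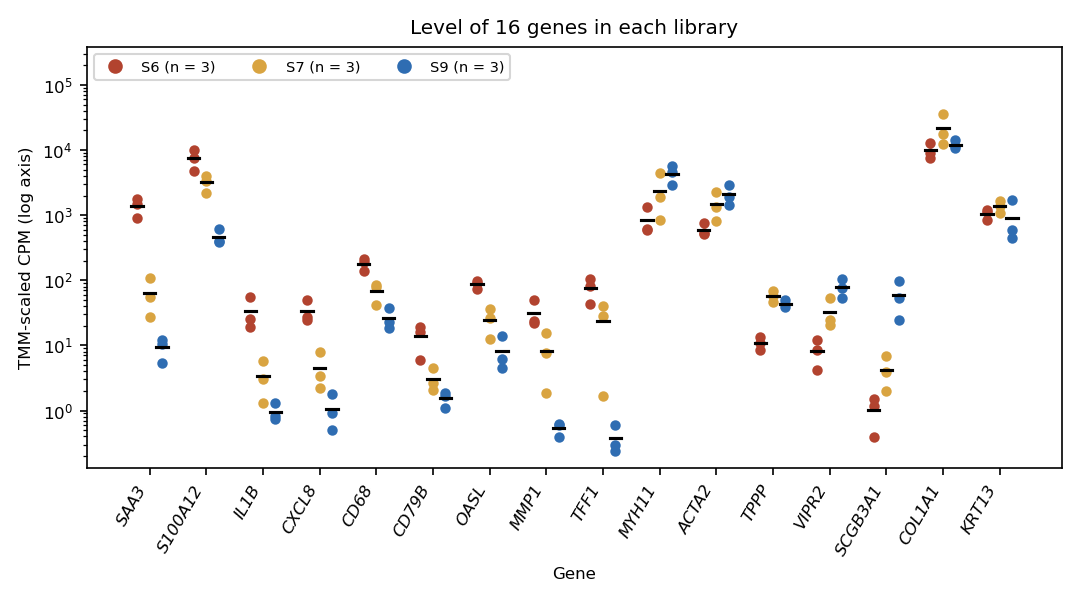
TMM-scaled CPM of 16 genes on a log axis, with a point per library and a black bar at the mean of each group of 3. SAA3 had a mean of 1385 CPM in S6 and 63.3 CPM in S7, MYH11 was at 856 CPM in S6 and 4363 CPM in S9, and the groups overlapped for KRT13.

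S7 and S6 differed in fewer called genes. SAA3, a serum amyloid A protein of the acute phase, was at 63.3 ± 40.2 CPM in S7 and 1385 ± 444 CPM in S6 (log2 fold change -4.45, SE 0.56, edgeR adjusted p = 0.0445). CHI3L2, a chitinase-like protein, was at 1.26 ± 0.789 against 25.7 ± 7.34 CPM, the interleukin-1 receptor chain IL1RAP at 2.37 ± 0.445 against 11.6 ± 2.53 CPM, and the kinase PIM1 at 21.1 ± 4.50 against 67.8 ± 3.41 CPM. TNFAIP3, an inhibitor of NF-kappaB signalling, was at 32.5 ± 6.52 against 96.7 ± 17.8 CPM, and the oxidase subunit CYBA had a log2 fold change of -1.49. Higher in S7 were the microtubule protein TPPP, at 57.0 ± 11.1 against 10.9 ± 2.40 CPM (log2 fold change 2.38, SE 0.22, edgeR adjusted p = 0.0303), GLIS2 (1.18), MXRA7 (1.16), CRIP2 (1.12) and NUMBL (1.04). In all, 19 genes were called by edgeR, 8 higher and 11 lower in S7, and 2928 had an unadjusted p below 0.05. All 19 lay near the threshold, with an edgeR adjusted p between 0.03 and 0.05. The libraries of the groups lay apart in 21.2% of genes, against a mean of about 10% over the possible splits, and the excess was not tested. By edgeR the count was 0 without S6_4, S7_2 or S9_1, where 2066 to 2743 genes had an unadjusted p below 0.05, 1 without S7_4, 2 without S6_2, S7_3 or S9_2, 3 without S9_4 and 10 without S6_3, and 0 in the 6 libraries with high mitochondrial counts, where 2253 had an unadjusted p below 0.05. DESeq2 called 1417 genes and limma-voom 306.

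No member of a gene list was called over all genes between S7 and S6, but 19 lists passed camera with the preset correlation. All 17 inflammatory cytokines and mediators had a negative log2 fold change (median -1.95), with 8 called when adjusted over the list alone, and this list also passed with an estimated correlation (adjusted p = 0.0255). IL1B was at 3.39 ± 2.27 against 33.3 ± 19.2 CPM and PTGS2 at 10.3 ± 3.11 against 52.0 ± 27.7 CPM. IL17A had 0 counts in S7 and 84 in S6, at least 28.1-fold lower against a floor of 3 counts over the group. The neutrophil list (median -1.78), macrophage list (-1.41), T and NK cell list (-1.53), B and plasma cell list (-1.90) and interferon list (-0.71) passed in the same direction, with 10, 16, 8, 10 and 11 members lower when adjusted over the list alone. With an estimated correlation the adjusted p of these 5 lists was 0.453 to 0.484. Without S6_3 the T and NK cell median was -0.98, and without both S6_3 and S7_3 it was -0.76 and that of macrophages -0.90. CD163 was at 22.3 ± 7.61 against 141 ± 106 CPM and MZB1 at 15.2 ± 10.9 against 89.2 ± 24.3 CPM. The smooth muscle list passed as higher (median 1.30, and 0.72 without S7_2), with 19 of 20 members called when adjusted over the list alone. With an estimated correlation its adjusted p was 0.453. ACTA2 was at 1463 ± 723 against 599 ± 127 CPM (edgeR adjusted p = 0.161). Basement membrane (median 0.65), fibroblast (0.64), endothelium (0.52), Schwann cell and nerve (0.68) and TGF-beta pathway lists (0.26) passed as higher, and glycolysis and hypoxia (-0.50), antioxidant (-0.35), immediate early (-0.75), cell cycle (-0.36) and oxidative phosphorylation lists (-0.21) as lower. With an estimated correlation the adjusted p of these 10 lists was 0.453 to 0.752. Adjusted over the list alone, 4 fibroblast, 4 endothelial, 1 Schwann cell and 1 immediate early genes were higher, and 1 glycolysis, 2 antioxidant and 5 immediate early genes were lower. The list levels of the libraries overlapped between S7 and S6 for the T and NK cell, endothelium, Schwann cell, cell cycle and oxidative phosphorylation lists. For smooth muscle the lowest S7 level, -0.550 in S7_3, was hardly above the highest S6 level, -0.551 in S6_2. Single libraries ended 6 of the 19 calls. The Schwann cell call was lost without S6_3, S6_4, S7_2 or S7_4 (medians 0.40 to 0.53, adjusted p 0.10 to 0.265) and the immediate early call without S6_2 (median -0.40, adjusted p = 0.0779). The oxidative phosphorylation call was lost without S6_3 (median -0.036, adjusted p = 0.357), with the length correction (-0.065 and 0.310, with alternatives from 3.5e-06 to 0.601) and without both S6_3 and S7_3 (-0.073 and 0.162). The TGF-beta call (adjusted p = 0.0498) was lost without S6_2, S6_3, S6_4, S7_3 or S7_4 (medians 0.15 to 0.33, adjusted p 0.0536 to 0.124) and in the 6 libraries with high mitochondrial counts (median 0.16, adjusted p = 0.0737). It was also lost, with a median as large or larger, without both S6_3 and S7_3 (0.27 and 0.0786), with the length correction (0.36 and 0.0505) and, with a median of 0.25, with at least 1 CPM in 3 libraries (0.0584), and over its alternatives the adjusted p ran from 0.0293 to 0.491. The cell cycle call was lost without S6_3 (median 0.090, adjusted p = 0.754), S7_2 (-0.085 and 0.599) or S7_4 (-0.21 and 0.0976), and its median was -0.79 without S7_3 and -1.0 in the 6 libraries with high mitochondrial counts. Other calls stayed but their medians moved. Without S7_2 the median was 0.38 for basement membrane, 0.28 for endothelium, -0.20 for antioxidant and -0.40 for immediate early genes. It was 0.40 for basement membrane without S7_3, -0.42 for immediate early genes without S6_3, 1.18 for the Schwann cell list without S6_2 and 0.83 for endothelium without both S6_3 and S7_3.

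The fibrillar collagen list passed as higher in S7 than in S6, with 24 of 24 members positive (median 1.0), 2 of them called over the list alone and none over all genes. It passed with the preset correlation, and with an estimated correlation its adjusted p was 0.484. S7_3 stood apart, with a list level of 1.41 against 0.13 and 0.18 in the other S7 libraries and 0.31 in S6_3, so the groups overlapped. COL1A1 was at 35155 CPM in S7_3, 12560 CPM in S7_2 and 17579 CPM in S7_4. Without S7_3 the median was 0.47, the lowest over the left-out libraries, and the list still passed, as it did in the 6 libraries with high mitochondrial counts (median 0.24). The collagen crosslinking list also passed as higher, with 19 of 19 members positive and none called, over all genes or when adjusted over the list alone, and list levels that overlapped (median 0.86, adjusted p = 0.491 with an estimated correlation). That call was lost without S7_3 (median 0.22, adjusted p = 0.134), stayed without both S6_3 and S7_3 (median 0.46), and was lost in the 6 libraries with high mitochondrial counts (median 0.11, adjusted p = 0.234). FBN1, the main protein of microfibrils, was at 952 ± 51.5 against 422 ± 85.7 CPM (edgeR adjusted p = 0.0915). COL1A1, COL3A1, FN1, MYH11, TGFB1, KRT5, KRT13, UPK1B, PECAM1, VEGFA and MKI67 were not called, and the 11 remaining lists did not pass (camera adjusted p 0.0757 to 0.876). Among these 1 protease and 1 urothelial gene were higher when adjusted over the list alone. Their medians were 0.41 for repair growth factors, 0.24 for squamous differentiation, 0.23 for mitochondrially encoded genes, 0.036 for basal epithelium, -0.034 for secretion (mean 0.0061), -0.062 for the unfolded protein response, -0.10 for proteases and for epithelial junctions, -0.17 for skeletal muscle, -0.20 for urothelium and -0.47 for adipocyte genes.

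Between S9 and S7 no gene passed. edgeR called 0 genes, with 1575 at an unadjusted p below 0.05 and a smallest adjusted p of 0.356, DESeq2 called 123 and limma-voom 0. The smallest p-values of the neutrophil list belonged to S100A12, at 468 ± 129 in S9 against 3186 ± 924 CPM in S7 (log2 fold change -2.77, SE 0.37, edgeR adjusted p = 0.356), and S100A9, at 74.6 ± 39.3 against 1371 ± 696 CPM. TFF1 was at 0.377 ± 0.197 against 23.4 ± 19.7 CPM, PSCA at 1.23 ± 0.713 against 36.0 ± 19.7 CPM and MMP1 at 0.545 ± 0.129 against 8.34 ± 6.87 CPM, none of them called. The groups' libraries lay apart in 17.2% of genes, against a mean of about 10% over the possible splits, and the excess was not tested. Without S7_2 or without S9_2 edgeR called 1 gene, lower in S9, as it did in the 6 libraries with high mitochondrial counts.

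Between S9 and S7 16 lists passed camera with the preset correlation, none of them with an estimated one, where their adjusted p was 0.142 to 0.619. Lower in S9 were cell cycle (27 of 27 members negative, median -0.88), fibrillar collagen (22 of 24 negative, median -0.88), collagen crosslinking (-0.55), proteases (-0.81), secretion (-0.76), cytokines (-1.05), neutrophil (-0.70), T and NK cell (-0.59), interferon (-0.40), squamous differentiation (-0.55), urothelium (-0.44), antioxidant (-0.33), oxidative phosphorylation (-0.20) and unfolded protein response lists (-0.25). Smooth muscle (0.43) and endothelium (0.30) were higher. List levels of S9 and S7 libraries overlapped for collagen crosslinking, smooth muscle, endothelium, urothelium, squamous differentiation, T and NK cell, interferon, cell cycle, antioxidant and unfolded protein response lists. Adjusted over the list alone, 5 secretion, 5 neutrophil, 4 cytokine, 2 protease and 1 urothelial genes were lower, and 1 cytokine was higher. The collagen values leaned on S7_3, with COL11A1, a fibrillar collagen chain, at 477 CPM there and at 5.02 and 16.3 CPM in S7_2 and S7_4, against 0.550 ± 0.435 CPM in S9. Without S7_3 the median was -0.43 for fibrillar collagen, -0.40 for the cell cycle, -0.26 for proteases and -0.45 for the neutrophil list, whose calls stayed, while the collagen crosslinking (median -0.14, adjusted p = 0.112), smooth muscle (0.15 and 0.151), endothelium (0.081 and 0.507) and squamous calls (-0.14 and 0.22) were lost. Without both S6_3 and S7_3 the smooth muscle (0.14 and 0.155), endothelium (0.064 and 0.449) and squamous calls (-0.15 and 0.295) were lost, and the median was -0.44 for fibrillar collagen, -0.16 for collagen crosslinking, -0.27 for proteases and -0.41 for the cell cycle. Without S9_2 the T and NK cell (median -0.35, adjusted p = 0.0665), antioxidant (-0.22 and 0.0560), smooth muscle (0.15 and 0.0782), endothelium (0.16 and 0.254), squamous (-0.22 and 0.323) and urothelial calls (-0.25 and 0.0779) were lost. Without S9_1 the T and NK cell (median -0.28, adjusted p = 0.0705), antioxidant (-0.19 and 0.0851), endothelium (0.24 and 0.0660), unfolded protein (-0.18 and 0.0732) and urothelial calls (-0.15 and 0.0551) were lost, and without S7_2 that of T and NK cells (-0.32 and 0.154). Without S7_4 the antioxidant (median -0.20, adjusted p = 0.0536), unfolded protein (-0.23 and 0.0605) and urothelial calls (-0.25 and 0.0782) were lost, and without S9_4 the unfolded protein call (-0.25 and 0.0528). In the 6 libraries with high mitochondrial counts the collagen crosslinking (median -0.037, adjusted p = 0.787), protease (-0.22 and 0.151) and unfolded protein calls (-0.20 and 0.0759) were lost, and the median was -0.23 for fibrillar collagen, -0.31 for the cell cycle, -0.46 for neutrophil, -0.68 for interferon, -0.94 for squamous, -1.20 for secretion and -1.25 for T and NK cell genes. With the length correction the oxidative phosphorylation (median -0.073, adjusted p = 0.0736, with alternatives from 1.2e-06 to 0.552) and antioxidant calls (-0.18 and 0.0708, from 0.000306 to 0.491) were lost, the unfolded protein median was -0.15, and without a filter on low counts the squamous call (-0.37 and 0.0946, from 0.000176 to 0.533). Further medians moved while the calls stayed. Without S9_4 the median was 0.68 for smooth muscle, -0.59 for antioxidant, -0.61 for interferon, -0.73 for urothelium, -1.04 for T and NK cell, -1.17 for secretion and -1.54 for squamous genes. Without S9_2 it was -1.40 for the cell cycle and -0.87 for collagen crosslinking, and without S9_1 -0.68 for cytokines, -0.31 for squamous and -0.26 for interferon genes. Without S7_2 it was 1.14 for smooth muscle and 0.54 for endothelium, and without S7_4 it was 0.28 for smooth muscle, -0.39 for neutrophil and -0.18 for interferon genes. The 14 other lists did not pass (camera adjusted p 0.0800 to 0.863), with medians from -0.79 for adipocyte genes to 0.56 for skeletal muscle, and the TGF-beta pathway had a median of 0.031 and a mean of -0.21.

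Across the 3 groups together, 415 genes differed by edgeR's F test, and 4295 had an unadjusted p below 0.05. Without S6_4 or S9_1 the F test called 0 genes (3331 and 3045 at an unadjusted p below 0.05), without S9_2 8, without S7_4 83, without S6_3 130, without S7_3 273 and without S6_2 641, and 0 in the 6 libraries with high mitochondrial counts (3172 at an unadjusted p below 0.05). DESeq2 called 3305 genes and limma-voom 2347. In the 2115 genes the S7 mean lay between those of S6 and S9 for 1990 (94.1%), at a median of 0.618 of the way from S6 to S9. By library this was 0.827 for S7_2, 0.487 for S7_3 and 0.556 for S7_4. These genes were picked by S6 and S9, which by itself moves an S6-like library above 0 and an S9-like library below 1. With genes picked at an unadjusted p below 0.05 without the library in question, left-out S6 libraries lay at 0.379, 0.0770 and 0.0655, S7 libraries at 0.828, 0.409 and 0.516, and S9 libraries at 1.11, 0.989 and 0.635. Leaving out an S7 library changes no S6 or S9 library, so the S7 positions and the 94.1% keep this pull towards the middle. Each left-out library was placed with its own genes and group means, so these positions are not on 1 scale. S9_4 lay at 0.635 and S7_2 at 0.828 when left out, but at 0.836 and 0.827 in the 2115 genes. S6_2 lay at 0.379 and S7_3 at 0.409 when left out, but at 0.138 and 0.487 in the 2115 genes. Since S9_4 and S6_2 helped to pick the 2115 genes, whether S7 overlapped S9 or S6 along this axis is not settled.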

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

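The length correction, the mitochondrial term, the 6 libraries with high mitochondrial counts, the mitochondrial genes left out, and the fit without S6_3 and S7_3 were chosen after seeing the data. DESeq2 size factors, upper-quartile scaling, both other filters, the length correction and the mitochondrial genes left out kept the counts of genes and lists within 1.5 times. The mitochondrial term did so too except for S7 against S6, with 2136 genes for S9 against S6, 553 for the 3 groups and 57 list calls. The cause of the changes below was not tested. For S9 against S6, 2115 genes became 4112 with DESeq2, 4061 with limma-voom, 7 in the 6 libraries and 1171 without S6_3 and S7_3, with 0 to 2076 when 1 library was left out. For S7 against S6, 19 genes became 1417, 306, 0 and 3 in the same fits, 52 on log2(FPKM + 1) (15 higher, 37 lower), 37 on log2(FPKM + 0.1), 4 with the mitochondrial term and 0 with only the 2 groups, with 0 to 10 by left-out library. For S9 against S7, 0 genes became 123 with DESeq2 and 1 in the 6 libraries, and 0 to 1 by left-out library. For the 3 groups, 415 genes became 3305 with DESeq2, 2347 with limma-voom, 227 on log2(FPKM + 1), 0 in the 6 libraries and 45 without S6_3 and S7_3, with 0 to 641 by left-out library. The 55 list calls became 2 with an estimated correlation, 5 with fry's directional test and 35 with its mixed test, which shared 28 with the 55, and lay between 50 and 63 by left-out library.

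A replicate block on the number in the sample titles gave 16 genes for S9 against S6, 1 for S7 against S6, 0 for S9 against S7 and 2 for the 3 groups. Number 1 occurs only in S9_1, so the block fits that library by itself and S9 is compared through S9_2 and S9_4. The fit without S9_1 gave 0 genes for S9 against S6, so an effect of the block cannot be told apart from the loss of this library. The block gave 52 list calls, of which 46 were among the 55. Of these 46, 10 medians moved by more than 1.5 times. In S9 against S6 macrophages went from -1.66 to -1.09, cell cycle from -1.35 to -0.68, oxidative phosphorylation from -0.40 to -0.26 and immediate early genes from -0.44 to -0.92. In S9 against S7 fibrillar collagen went from -0.88 to -0.45, crosslinking from -0.55 to -0.15, proteases from -0.81 to -0.31, neutrophil from -0.70 to -0.25, interferon from -0.40 to -0.26 and cell cycle from -0.88 to -0.15. The 9 lost were the TGF-beta pathway in S7 against S6 (median 0.22, adjusted p = 0.0505), proteases (-0.70 and 0.0599), growth factors (0.23 and 0.120) and unfolded protein response (-0.16 and 0.0771) in S9 against S6, and squamous (-0.32 and 0.129), T and NK cell (-0.33 and 0.118), endothelium (0.22 and 0.232), oxidative phosphorylation (-0.068 and 0.137) and unfolded protein lists (-0.11 and 0.137) in S9 against S7. The numbers were not a block in the main fit, as set beforehand, because no label says what they stand for. The correlations between libraries do not settle this, and a link between some same-numbered libraries stays open. Deviations of same-numbered libraries correlated at 0.138, 0.132 and 0.0226 for S6 and S7, at -0.0649 and 0.127 for S6 and S9 and at 0.0640 and 0.0201 for S7 and S9, 6 of these 7 being positive. Of the 20 pairs with different numbers 9 were positive and the highest was 0.103 (S7_3 and S9_4), and S6_4 correlated better with S7_3 (0.0445) than with S7_4.

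The 82 calls of named genes kept their sign in each fit that tested them, and 0 to 70 remained called when 1 library was left out. Because the fits share libraries with the fit that picked these calls, the kept signs say little about how stable the calls are. The cell cycle list in S7 against S6 reversed without S6_3 (median 0.090, with -0.79 to 0.090 by left-out library). For genes with 0 to 3 counts in a group, depth limited the fold to a bound or a wide interval.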

Other observations

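All tests of explanations here were chosen after the values were seen, except the counts over other groupings. The genes of the next paragraph were also chosen after their values were seen.

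Some abundant genes outside the lists were also called between S9 and S6. Lower in S9, the invariant chain CD74 was at 555 ± 228 against 2583 ± 2136 CPM (edgeR adjusted p = 0.0426), the class II gene RLA-DR-ALPHA at 316 ± 134 against 1739 ± 1370 CPM (0.0313) and B2M at 1278 ± 333 against 2662 ± 383 CPM (0.0377). CD74 reached 4963 CPM in S6_3 and 831 CPM in S6_2. The acute-phase protein ORM1 was at 4.56 ± 4.72 against 459 ± 377 CPM (0.0270), the transcription factor CEBPD at 216 ± 11.6 against 655 ± 101 CPM (0.00881) and the interleukin-1 receptor antagonist IL1RN at 16.4 ± 12.4 against 251 ± 76.4 CPM (0.0196). Higher in S9 were the latent TGF-beta binding protein LTBP4 at 1467 ± 421 against 266 ± 88.0 CPM (0.0244), FHL1 at 991 ± 365 against 229 ± 36.7 CPM (0.0248), the filamin FLNC at 375 ± 135 against 70.8 ± 5.29 CPM (0.0195) and the receptor NOTCH3 at 356 ± 20.7 against 149 ± 36.5 CPM (0.0164). As for all calls between S9 and S6, none was made without S9_1, where the count was 0.

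The 86 tested members of the cytokine, neutrophil, macrophage, T and NK cell and B and plasma cell lists had a median log2 fold change of -2.09 in S9 against S6. After the length correction it was -1.94, which argues against the length trend as the whole cause, and without S6_3 it was -1.64, so the fall did not rest on that library alone. Dilution of all other cells by more muscle would lower epithelial genes as well. The 71 members of the 5 epithelial lists had a median of -0.30, with a lowest quartile bound of -0.97, and 51 were negative. The rule for excluding dilution asked for a gap to the leukocyte median above their SD of 1.87, and it was not met. That SD is a spread between genes and not the error of the median, so the rule cannot decide the question. The epithelial list medians ran from -0.19 for basal epithelium to -1.07 for secretion. A positive log2 fold change was found for 18 of 18 endothelial genes (median 0.81), 14 of 15 fibroblast genes (0.40) and 11 of 14 Schwann cell and nerve genes (1.21). These lists did not fall, so the values show no dilution that lowers all other cells alike. If a piece with more muscle wall also held more vessels, fibroblasts and nerve, these lists would rise too. They thus cannot exclude more muscle wall in the piece. Dilution of some of the other cells, or as a part of the fall, stays open. Fewer leukocytes in the S9 tissue and lower expression of these genes, including S100 genes that squamous epithelium also makes, both stay open as untested hypotheses, and the meaning of the codes is unknown.

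The 20 smooth muscle genes had a median log2 fold change of 1.91 in S9 against S6, and 1.96 after the length correction, which argues against the length trend. Within groups the members moved together, with a median pairwise correlation of deviations of 0.878 across the 9 libraries. Of 1000 random lists matched on expression, 870 held no repeated gene, and their 95th percentile was 0.130. Lists of unrelated genes are a low bar for markers of a cell type, so the comparison was likely to be passed. Such joint movement is what a varying share of muscle wall in the sampled piece would give, and a shared regulation of these genes could give it too. A candidate explanation is thus the piece of tissue taken, and a difference in the tissue between the groups stays open as untested.

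Mitochondrially encoded genes were low in S6_4, S7_3 and S9_4. Less mitochondrial RNA would lower all of them, but CYTB, ND4 and ND5 had a median log2 difference of -0.15 between these 3 and the other 6 libraries with group in the fit, while ATP6 had -6.75. With mitochondrial genes left out, 1 nuclear gene differed, and the highest of the other choices of 1 library per group, 27 in all, also gave 1, as 5 of them did, so a library batch that also moves nuclear genes can be neither shown nor excluded. With them kept in, the nuclear genes ADORA1 and P2RX4 were higher in the 3 libraries, by 4.19 and 3.31 on the log2 scale, and gained 1.53% of the mitochondrial CPM lost. A mitochondrial sequence variant or nuclear copies that take the reads may still account for the split, since reads dropped before counting leave no trace in the table and no genome was used here. No biological explanation was tested.

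Of 100 drawn splits of the 9 libraries, of 280 possible, 1, the real one, gave as many genes by the F test as the real 415, and the highest other gave 55. The share was thus under 0.05, which argues against a random split only if the 9 libraries are independent. The labels do not say so, and the test cannot separate the codes from an animal or batch shared by the libraries of a code. The F test also called 0 genes without S6_4 or S9_1. For the lists, 1 of 100 splits, the real one, gave 55 calls, but the highest other gave 53 and the median of the others was 39. The preset correlation thus passed many lists under groupings that mix the codes, which points to gene lists that vary together between libraries. The 10 splits of 6 libraries are too few for a share under 0.05. For S9 against S6 the real split, 1 of 10 with as many genes, gave 2115 and the highest other 3, and for S7 against S6 the real split, also 1 of 10, gave 19 and the highest other 5. For S9 against S7 the real split gave 0, all 10 gave as many, and the highest other gave 3.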
